A study of Danio rerio with 38 samples.

How the data were processed

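The series profiled chromatin, DNA methylation and RNA of mature zebrafish sperm, with muscle as the comparison tissue for DNA methylation and whole fish as the reference for RNA. Per the labels' protocols, ChIP-chip (chromatin immunoprecipitation read on tiling arrays) used sperm chromatin released with 15 units of micrococcal nuclease for 5 minutes and 2 μg of antibody. The 7 targets were H3K4me3, H3K4me2, H3K14ac, H3K27me3, H3K36me3, H3K9me3 and H2AFV, the zebrafish H2A.Z variant. MeDIP-chip, in which an antibody pulls down DNA carrying 5-methylcytosine, started from 4 μg of DNA sheared to about 400 bp. Each of these 9 sample groups has 2 replicates on 2 slides each, so that it holds 4 samples, and sperm RNA has 2 samples. The series has 38 samples in 10 groups.

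The 9 chromatin and methylation tables hold log2 values that the authors made and deposited, with 1 value per probe, of mean immunoprecipitated over mean input signal. Per the series' design text, the mean input of all ChIP tables came from the same 3 input channels, and for MeDIP the labels give an input channel on each array. The normalization, software and genome build of these tables are not given in the sources used here. Because the replicates were pooled before deposit, no value in these tables has a replicate error, and every statement on them is a description with no p-value. The labels place H3K14ac and H3K27me3 in opposite channels of the same arrays, with the common input taken from other arrays. The channel of the second H3K27me3 replicate carries the label of replicate 1, and the partner channels of H2AFV, of second replicates of H3K4me3 and H3K4me2, and of the second H3K9me3 replicate are labelled as failed or pilot experiments, so that what the pooled values are means of is not fully certain.

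The 2 sperm RNA arrays were deposited as scanner output with intensity values per spot, read with Agilent Feature Extraction 9.5.1, per the file headers. Per the labels, sperm RNA carried Cy5 and whole-fish RNA Cy3 on both arrays and the labelled material was the polyadenylated fraction. The series' design text speaks of dye swaps throughout, but these labels show none for RNA. The same files hold Agilent's log10 ratio of processed red over green signal, per the file headers; it was turned to log2 for an alternative setting. Both arrays came from the same slide and scan, which left no batch to test. The labels call the replicates biological but do not say whether they came from separate males, so that p-values measure only the spread between these samples.

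For RNA, background was corrected by normexp with an offset of 50 and each array was normalized by loess with control spots at weight 0, using limma 3.58.1 in R 4.3.3. Repeated spots of a probe were averaged, and probes were kept where either channel was well above background on both arrays. A gene with several probes was represented by the brightest. The log2 ratio of sperm over whole fish was tested against 0 with lmFit and eBayes, with Benjamini-Hochberg adjustment at 0.05 and the same sign required on both arrays. This test leaves out any spread of the whole-fish reference, which was a single RNA source against which no other whole-fish sample was run. Precision was limited by the 2 arrays. Where a gene was not well above background in one channel on either array, the ratio is a bound, written as at least N-fold; it compares the bright channel with, on each array, the higher of the dimmest signal well above background and the dim probe's own, after loess and Aquantile scaling. Where the probe's own signal was the higher, the bound equals the loess ratio. Bounds hold under this scaling only, carry no error and are open to dye bias. A bound close to equal signal does not show that a gene differed.

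Gene names came from the reference table of the GRCz12tu assembly: of 21495 probes, 7352 were named through a RefSeq accession, 605 through a symbol, 2346 through a synonym, and 11192 kept the name in the file, giving 17980 gene names. Members of a list were matched on the present symbol or on the file's name. The plan had also matched list members through synonyms, which was not done. A member listed under an older symbol can therefore be missing from its list. An old name that is now the symbol of another gene was not counted, and the keys dld and dldh, which have exchanged places between the file and the reference, were left out. Both of these rules were added after the values had been seen. The probe that the file calls sycp3 is listed under chpt1 in the reference and was therefore not counted in the meiosis list.

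The 18 gene lists, the tests and the settings were fixed before the data were examined, except where stated. Lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. With an estimated correlation camera rests on the spread between 2 arrays. Every list then had an adjusted p of 0.838 to 0.940 in limma's camera, so that this setting could hardly have passed any list. Fry tests a list against no change rather than against the other genes. The rule for named genes took the 10 with the largest rise and the 10 with the largest fall past the threshold, and from each list the 2 members with the highest and the 2 with the lowest ratio. Not every list member that this rule names is reported here. No gene passed the threshold, so genes are named in its place that were at least 2-fold the same way on both arrays, were well above background on both arrays in the brighter channel (called bright), and had an ordinary symbol, a choice made after their values had been seen.

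For the tables of chromatin and methylation, each table was centred on its median, and a probe was called enriched at a centred log2 value of at least 1. Of 395779 probes 339592 were measured, and the other 56187 were blank in all 9 tables. Probe positions were not used here. The numbers in the probe names stood in for the tiling order, a change from the plan, which had assumed gaps in base pairs: a region was a run of at least 3 enriched probes whose numbers differed by at most 2. Neighbouring probes had alike values in this order, with r between successive probes of 0.894 for H3K4me3. Enrichment of pairs of marks was set against the number expected from independence and against 100 circular shifts of a table along the probe order, and region counts against 20 such shifts. Shares are given with 95% Wilson intervals, which cover counting error only and take probes as independent, and with the range over 9 consecutive stretches of the probe order. These stretches hold only the 312444 probes of the main number series, so that the ranges leave out the other probes. The calculations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

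Both calculations were tested on simulated data. With 200 of 6584 genes changed and the spread drawn from the fitted prior, the RNA test recovered 0% of changes of a true log2 size of 1, 6% at size 2, 38% at size 3 and 72% at size 4. It called 0 genes in the wrong direction and 4 unchanged genes. The prior was fitted over all tested genes together, so that these shares need not hold for genes bright in sperm. The region search found all 200 simulated bivalent regions among 339592 probes. These regions were set far above the threshold of enrichment relative to the simulated noise, so that full recovery followed from the settings. In the data bivalent probes had a median H3K27me3 of 1.24, closer to the threshold. The simulation checks the calculation and does not show how many weaker regions would be found.

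Alternatives covered the background correction, the dye normalization, the filter on dim probes, outlier spots, the probe per gene, the moderation, each array left out, the set test, the centring, the threshold of enrichment, smoothing over neighbours and the rule for regions. Outlier spots numbered 0 and 3 on the arrays. Some rules for comparing settings were set after results had been seen: a value of an uncalled gene or list counted as reversed only where a setting called a direction, ratios of pairs were compared only with at least 1 expected probe, and methylation medians only for marks with many enriched probes. Chromatin at the gene lists and chromatin by sperm RNA were planned but not made, since the tables do not pair probes with genes and no annotation of the tiling probes was used here.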

Results

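Sperm chromatin was profiled for 6 histone modifications and the histone variant H2AFV, DNA methylation was profiled in sperm and muscle, and sperm RNA was compared with whole-fish RNA. H3K4me3 and H3K4me2 mark promoters and enhancers that are open or poised, H3K14ac is an acetylation of active chromatin, H3K36me3 marks transcribed gene bodies, H3K27me3 is the mark of Polycomb repression, and H3K9me3 marks heterochromatin. The title of the series names blocks of multivalent chromatin at genes for embryo development, so the questions were how far these marks lie together in sperm, how they relate to DNA methylation, and which transcripts mature sperm hold. The chromatin and methylation tables gave 339592 measured probes with 1 pooled value each and no replicate error. The RNA arrays gave 42990 spots per array and 2 replicates. Sperm RNA was well above background at 4270 spots on array 1 and 2891 on array 2, against 15713 and 15666 for whole-fish RNA. The brightest percentile of spots began at a foreground intensity of 314 and 169.5 in the sperm channel and 7263 and 7225 in the whole-fish channel.

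Among bright genes with an ordinary symbol, the highest ratios of sperm over whole-fish RNA belonged to single genes of unlike functions, and no single gene passed the test. Several transcripts known only by a clone or cluster name had higher ratios and are not named. ATP6, the mitochondrially encoded subunit of ATP synthase, had a log2 ratio of 8.83 ± 0.66 (SD, n = 2), and 3.83 with median centring. The mismatch repair gene msh6 stood at 7.13 ± 0.86, and 1.08 with median centring, and vangl2, a core component of planar cell polarity, at 6.83 ± 1.86. The vangl2 ratio turned to -1.38 with median centring of the arrays. The ratio of apoeb, an apolipoprotein E, was 6.82 ± 0.49 at its brightest probe, and its 8 tested probes ranged from 1.41 to 6.82. Its value was -0.23 with median centring. These genes, like the others named in this and the next paragraph, were chosen after their values had been seen, from those at least 2-fold the same way on both arrays: 152 of 269 such genes on the sperm side and 2 of 7 on the whole-fish side were bright and had an ordinary symbol.

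Some genes of cilia and sperm formation were among the same set. The polyglutamylase subunit tpgs1, which modifies the tubulin of axonemes, had a log2 ratio of 5.72 ± 1.93 (SD, n = 2), and 1.81 with median centring. The ratio of ccdc62, a coiled-coil protein of developing spermatids in mice, was 5.03 ± 0.51, and 1.73 with median centring. The cilia and flagella associated gene cfap263 was at least 30.3-fold brighter in sperm after loess, since whole fish was not well above background on either array, and its log2 value was 2.45 with median centring. The lysosomal protease gene lgmn stood at 4.86 ± 1.35, with its 2 probes at 0.61 and 4.86, and had a value of -1.07 with median centring. The calcium-binding parvalbumin gene pvalb6 stood at 4.74 ± 0.55, with probes at 4.13 and 4.74, and at 2.02 with median centring. The cytoplasmic actin gene actb2 had 4.63 ± 0.70 at its brightest probe, but its 3 probes ranged from -0.20 to 4.63, and median centring gave -3.85. On the low side were hbba1, an adult beta-globin of red blood cells, at least 3.58-fold dimmer in sperm, and cldnd, a claudin abundant in fish eggs, at -1.62 ± 0.79. With median centring, where the all-gene median was -1.87, hbba1 stood at -7.25 and cldnd at -7.03. Limma's adjusted p lay between 0.229 and 0.541 for the 10 genes with high ratios, and was 0.644 for hbba1 and 0.643 for cldnd. In Agilent's ratios all of these genes but actb2 passed in the same direction. With median centring ATP6, msh6, ccdc62, cfap263 and pvalb6 passed as higher, and vangl2, actb2, hbba1 and cldnd as lower.

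Over all 6584 genes tested, limma called 0 genes higher and 0 lower in sperm RNA, and 496 genes had an unadjusted p below 0.05. By mean ratio with no test, genes at least 2-fold higher in sperm RNA numbered 526 and genes at least 2-fold lower in sperm RNA 51, and on both arrays separately 269 and 7. With replicate 1 left out the counts on the remaining array were 450 and 7, and with replicate 2 left out 782 and 156. These compare with the mean-ratio counts of 526 and 51, not with the counts that require both arrays. Of the genes on the arrays, 801 were well above background in sperm on both arrays and 6514 in whole fish, 734 in both, and 52 in sperm on both arrays and in whole fish on neither, each counted where a single probe of the gene met the condition. Across genes, which are not independent replicates, the ratios of the 2 arrays correlated with r = 0.648, and with r = 0.733 over the genes above background in sperm.

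The split between high and low genes depended on the scaling and on the filter. Loess set the median log2 ratio of all tested genes at -0.02, whereas it was -1.38 in Agilent's own ratios and -1.87 with median centring. In limma with Agilent's ratios 372 genes were higher and 2675 lower (12.2% higher), and with median centring 77 were higher and 5979 lower (1.27% higher). Among the 734 genes above background in both channels, a filter that by itself selects genes bright in sperm (median 1.01 with the scaling unchanged), 211 were higher and 7 lower (96.8% higher). The named genes kept their ratios there, and only the p-values changed with the refitted moderation. Limma's adjusted p for ATP6 went from 0.229 to 2.03e-25. Even gdf3, at 0.69 and 4.69 on the arrays, had an adjusted p of 0.0015 in limma. These calls therefore hardly weigh the spread of a single gene between the arrays. No background subtraction, no filter on dim probes, outlier spots left out, the mean over probes, an added 2-fold minimum and an intensity trend each left 0 higher and 0 lower. On simulated data of this design the test recovered 72% of changes of a true log2 size of 4 and 6% at size 2. The simulated spread came from all tested genes together. In the data the named genes with log2 ratios of 4.63 to 8.83 were not called, so that 72% need not hold for genes bright in sperm.

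Transcripts of ribosomal proteins, the structural parts of ribosomes, rose as a group in sperm relative to the other genes with loess, but the direction of the group turned with median centring (median -4.80, adjusted p = 0.467). Of 62 tested members 53 were above background in sperm on both arrays, and the median log2 ratio was 1.70. The highest were rps27a at 3.36 ± 1.52 (SD, n = 2) and rps14 at 3.02 ± 1.06, and the lowest were rpl7l1 at -0.33 ± 0.82 and rpl36, not well above background in sperm. The bound for rpl36 was 1.13-fold dimmer, but its log2 ratio was 0.01 with no background subtraction. With limma's camera the adjusted p was 6.09e-21, and adjusted p = 0.838 with an estimated correlation. Fry gave an adjusted p of 0.480 in limma. Over all genes 0 of the 62 members were called, and 7 were higher when adjusted over the list alone. In Agilent's ratios the median of the list was -0.05, above the all-gene median of -1.38.

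Genes of sperm and the flagellum also rose as a group in sperm RNA, in each of the scalings run. Of 11 tested members 6 were above background in sperm on both arrays, against 7 in whole fish, and the median log2 ratio was 1.60, or 0.97 for 17 genes with no filter on dim probes. Median centring gave a list median of 0.22 and Agilent's ratios 3.98. The ratio of cfap20, which encodes a protein of axonemal microtubules, was 4.53 ± 2.28 (SD, n = 2), and -0.55 with median centring. The lowest members were zmynd10, an assembly factor of dynein arms, at -0.01 ± 0.03 and efhc2, a ciliary EF-hand protein, at 0.03 ± 0.14, both not well above background in sperm. With limma's camera the adjusted p was 5.4e-05. With an estimated correlation, which was -0.02 for this list, camera gave an adjusted p of 0.838, as it did for most lists. That value therefore does not show that correlated members made the rise. Fry gave an adjusted p of 0.222 in limma. Over all genes 0 members were called, and 3 were higher when adjusted over the list alone.

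Genes of the egg and of the liver fell as groups in sperm RNA. The 13 tested oocyte genes had a median log2 ratio of -0.48 (-1.44 on array 1 and -0.24 on array 2), with cldnd at -1.62 ± 0.79 (SD, n = 2) and the oocyte linker histone h1m at -1.47 ± 0.98 at the low end. The RNA-binding gene ybx1, which is expressed in many tissues, stood at 0.29 ± 1.07 and the egg envelope gene zp3a.1, not well above background in sperm, at 0.06 ± 0.00. The adjusted p of camera in limma was 0.015 for the oocyte list, and adjusted p = 0.838 with an estimated correlation. The 18 tested liver and plasma genes had a median of -0.29 (-0.78 on array 1 and -0.23 on array 2), with the protease inhibitor gene serpina1 at -1.43 ± 1.19. The yolk protein gene vtg3 was at least 2.55-fold dimmer in sperm. The highest of this list were apoeb, named above, and the apolipoprotein A-I gene apoa1a at 0.52 ± 1.44. Camera gave an adjusted p of 0.0123 in limma for the liver and plasma list, and adjusted p = 0.838 with an estimated correlation; Agilent's ratios gave 0.067 and median centring 0.129. Fry gave adjusted p values of 0.649 for oocyte and 0.668 for liver and plasma in limma. Over all genes 0 members of either list were called, and adjusted over the list alone 1 gene of the liver and plasma list was higher and 0 of the oocyte list.

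Genes of white blood cells had a high median without passing the test. The 10 tested leukocyte genes had a median log2 ratio of 1.31 (1.31 on array 1 and 0.76 on array 2), with 5 above background in sperm on both arrays. The invariant chain gene cd74a, which serves antigen presentation, stood at 3.21 ± 0.51 (SD, n = 2) and the macrophage perforin gene mpeg1.1 at 3.15 ± 2.53; with median centring these values were -2.51 and -0.30. The myeloid factor cebpa and the lysozyme gene lyz were not well above background in sperm. The bound for cebpa was 1.13-fold dimmer, but its log2 ratio was 0.03 with no background subtraction. Limma's camera gave an adjusted p of 0.105, while it gave 0.0121 with no background subtraction, 5.77e-05 in Agilent's ratios and 0.0356 with median centring. It gave 0.242 with no filter on dim probes, where the median of 17 genes was 0.04, and adjusted p = 0.838 with an estimated correlation, and limma's fry gave 0.480. Over all genes 0 leukocyte genes were called, and 2 were higher when adjusted over the list alone.

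Among the lists of other tissues none passed. The 17 skin and connective tissue genes had a median log2 ratio of 0.07 (adjusted p = 0.0761 by limma's camera, and 0.0493 with no background subtraction). The keratin genes krt5 and krt4 differed between the arrays, at 2.71 ± 2.92 and 1.82 ± 2.46 (SD, n = 2). The lowest members were krt18a.1 and the fibronectin gene fn1b, both not well above background in sperm, with bounds of only 1.01-fold and 1.16-fold dimmer. The 24 skeletal muscle genes had a median of -0.21, with the troponin gene tnni2a.4 at 1.17 ± 0.26 and the actin gene actc1b at 0.73 ± 0.01, the troponin gene tnnt3b at -1.22 ± 1.08, and the creatine kinase gene ckma at least 1.97-fold dimmer in sperm. The 10 brain and neuron genes had a median of -0.06, with 0 above background in sperm, the glial filament gene gfap at 0.02 ± 0.09 and the calmodulin gene calm1a at -0.39 ± 0.23. The 9 erythrocyte genes had a median of -0.08, whereas camera ranked the list on the high side. The embryonic globin gene hbbe2 was at least 3.42-fold brighter in sperm and the heme enzyme gene hmbsa stood at 0.30 ± 0.67. The red cell skeleton gene epb41b was not well above background in sperm, with a bound of only 1.14-fold dimmer. The 4 tested genes of testis somatic cells, among them the steroid synthesis genes star at 0.06 ± 0.06 and cyp17a1 at 0.02 ± 0.06, had a median of 0.01 and 0 above background in sperm. Limma's camera gave adjusted p values of 0.276 for skeletal muscle, 0.312 for brain, 0.927 for erythrocytes and 0.892 for testis somatic cells, and adjusted over the list alone 1 erythrocyte gene was higher. With median centring the skin list (median -1.92) and the testis list (-0.71) turned to the low side, and in Agilent's ratios the testis list did (-1.41), without passing.

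Germ line, meiosis and energy genes likewise did not pass as lists. The 10 germ line genes had a median log2 ratio of -0.12 and a mean of 0.07, with the piRNA pathway gene gtsf1 at 2.52 ± 1.34 (SD, n = 2), the Piwi gene piwil1 at 0.56 ± 0.81, and the germ cell genes nanos3 and ca15b at least 1.44-fold and 2.25-fold dimmer in sperm. The 3 tested meiosis genes, the chromosome axis gene hormad1, the double-strand break gene spo11 and the recombination gene psmc3ip, had a median of -0.06 and 0 above background in sperm. The 44 genes of mitochondrial respiration had a median of 0.27 (-0.04 on array 1 and 0.18 on array 2), from cox7c at 1.76 ± 1.66 and ndufa6 at 1.74 ± 0.51 to atp5f1d at -0.76 ± 0.48. The 20 glycolysis genes had a median of 0.10, from gapdhs, the sperm form of glyceraldehyde-3-phosphate dehydrogenase in mammals, at 1.82 ± 1.29 and pkma at 1.22 ± 0.59 to pgk1 at -0.72 ± 0.61. Both energy lists turned to the low side with median centring, with medians of -3.74 and -3.38 against -1.87 for all genes, without passing. Limma's camera gave adjusted p values of 0.412 for germ line, 0.839 for meiosis, 0.105 for mitochondrial respiration and 0.618 for glycolysis, and 0 members were called either over all genes or when adjusted over the list alone.

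Genes that pattern the embryo were near the detection limit in sperm RNA. Of 43 hox genes on the array 9 could be tested, all through the whole-fish channel, and 0 were above background in sperm. Their median log2 ratio was 0.01 and their mean -0.02, from hoxb8a at 0.08 ± 0.11 (SD, n = 2) to hoxb5b, at least 1.01-fold dimmer in sperm. Of 65 other developmental transcription factors 1, the homeobox gene tlx2 at 1.12 ± 0.56, was above background in sperm on both arrays; evx1 stood at 0.94 ± 1.31, isl2b at -0.67 ± 0.37, and foxa was at least 1.24-fold dimmer in sperm. Of 17 genes of developmental signalling 1 was above background in sperm, the maternal Vg1 homologue gdf3 at 2.69 ± 2.83, with arrays at 0.69 and 4.69, and -0.17 as the mean over its probes; her6, a Notch target, stood at 0.87 ± 1.12 and aldh1a2, of retinoic acid synthesis, was at least 1.07-fold dimmer in sperm. The median of this list was -0.02 and its mean 0.19. The 5 pluripotency-associated genes had a median of -0.07 and 0 above background in sperm, with klf2a at 0.06 ± 0.11, and mycb and pou5f3, the zebrafish counterpart of Oct4, at least 1.07-fold and 1.04-fold dimmer in sperm. Limma's camera gave adjusted p values of 0.839 for hox genes, 0.618 for the other transcription factors, 0.839 for signalling and 0.618 for pluripotency. Over all genes and adjusted over each list alone 0 members were called. The bounds in this paragraph lie close to equal signal and are no evidence that these genes were lower in sperm. With median centring the hox (median -0.35), transcription factor (-0.80) and signalling (-0.61) lists turned to the high side relative to other genes, and the hox list did in Agilent's ratios (-1.06), without passing.

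**Figure D1:**
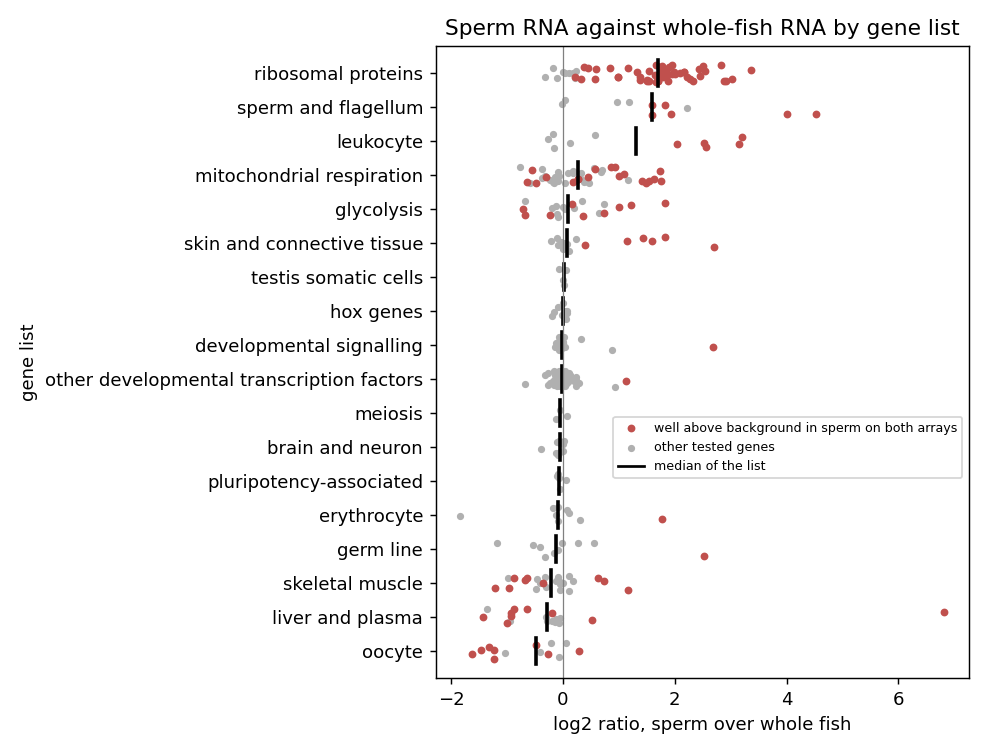
Each point is the log2 ratio of sperm over whole-fish RNA of a tested gene (mean of 2 arrays after loess, horizontal axis) in each of 18 gene lists (vertical axis), red where sperm was well above background on both arrays, with a black bar at the list median. The medians reach 1.70 for ribosomal proteins, which turned to -4.80 with median centring, and 1.60 for sperm and flagellum, and are lowest for oocyte genes at -0.48.

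Most of the enriched chromatin in sperm carried methylated H3K4. H3K4me2 was enriched at 99826 probes (29.4%, 95% Wilson interval 29.2 to 29.5) and H3K4me3 at 78437 (23.1%, 23.0 to 23.2). H3K36me3 was enriched at 11544 probes (3.40%, 3.34 to 3.46), H3K27me3 at 7207 (2.12%, 2.07 to 2.17) and H3K14ac at 3076 (0.906%, 0.874 to 0.938). H3K9me3 was enriched at 219 probes and H2AFV at 74, and the values of these tables had an SD of 0.29 and 0.25 against 0.94 for H3K4me3. H3K4me3 formed 7940 regions of at least 3 probes, the longest of 88 probes, and H3K27me3 formed 828, the longest of 36. Over 9 consecutive stretches of probes the share enriched for H3K27me3 ranged from 0.625% to 3.02%, and that for H3K4me3 from 19.9% to 26.8%. A difference in the number of enriched probes between marks includes differences between antibodies, and it has no replicate check.

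H3K27me3 in sperm lay mostly on chromatin that also carried H3K4me3. Of the H3K27me3 probes 83.6% were enriched for H3K4me3, against 23.1% of all probes, giving 6026 bivalent probes where independence would give 1665, 3.62 times as many. Circular shifts of a table gave 1392 to 1961. Part of H3K36me3 lay at the same probes, 28.8% of its probes being enriched for H3K27me3 and 46.0% for H3K4me3. Enrichment for H3K27me3 and H3K36me3 was found at 3325 probes against 245 expected (13.6 times). All of H3K4me3, H3K27me3 and H3K36me3 were enriched at 3180 probes, in 351 regions, against 56.6 expected. The 56.6 takes all 3 marks as independent, although pairs of them were not. Each mark was measured in its own immunoprecipitation, so that marks at the same probe need not lie on the same nucleosome. H3K4me3 and H3K4me2 overlapped at 73570 probes (3.19 times the number expected). H3K14ac lay with H3K4me3, at 2477 probes against 710 expected (3.49 times), which is 80.5% of its probes. With H3K27me3 it lay at 54 probes against 65.3 expected, within the 30 to 109 of shifted tables, and at 1.48 and 1.26 times the number expected with a threshold of 0.5 and in the top 5% of probes (H3K14ac and H3K27me3 observed over expected).

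The overlap of H3K27me3 with H3K4me3 was most frequent at intermediate levels of H3K4me3. The share of probes enriched for H3K27me3 was 0.170% where centred H3K4me3 was below 0, 8.08% between 1 and 1.5, 11.3% between 1.5 and 2, 2.88% between 2 and 2.5, and 0.234% (95% Wilson interval 0.119 to 0.462) at 2.5 and above. Within the top 5% of probes of each table, bivalent probes accordingly numbered 479 against 849 expected (0.564 times). Across all probes, which are not independent replicates, H3K4me3 and H3K27me3 had a Pearson r of -0.00 and a Spearman rho of -0.08. None of these comparisons has a replicate check.

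**Figure D2:**
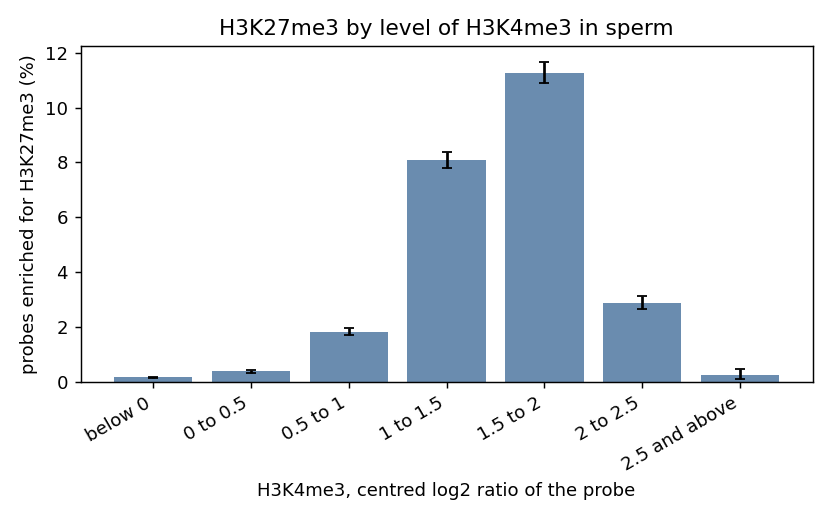
Bars give the percentage of probes enriched for H3K27me3 in sperm (vertical axis) by the centred log2 H3K4me3 ratio of the probe (horizontal axis), with 95% Wilson intervals that cover counting error only. The share is highest, at 11.3%, for H3K4me3 between 1.5 and 2, and is 0.234% at 2.5 and above.

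Bivalent probes formed runs along the probe order, but the number of runs was no separate evidence for blocks. Runs of at least 3 probes enriched for H3K4me3 and H3K27me3 numbered 757 and held 4171 probes, with a median length of 4, and 68 of them had at least 10 probes. Shifted tables gave at most 213 runs, so that the excess was about that of bivalent probes themselves, and in the top 5% of probes there were 41 runs where shifted tables gave up to 107. The longest, starting at probe WH_10_P0173639, spanned 36 probes with a mean centred H3K4me3 of 1.91, H3K27me3 of 1.41 and H3K36me3 of 1.47. Another of 27 probes, starting at WH_10_P0173555, lay just before it in the probe order, with H3K4me3 of 1.68 and H3K27me3 of 1.31. The next had 24, 24 and 21 probes, with H3K27me3 between 1.32 and 1.39. In all of these 5 regions H3K14ac was below 0.22 and H2AFV between 0.24 and 0.38. The genes at these probes were not identified here.

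Multivalent regions, in which H3K4me3, H3K27me3, H3K14ac and H2AFV were all enriched over at least 3 successive probes, numbered 0. At single probes all 4 marks were enriched at 1 probe, and 17 probes carried H3K4me3, H3K27me3 and H3K14ac against 15.1 expected. The numbers expected in this paragraph take all marks as independent of each other, although pairs of them were not. The 17 were among 6026 bivalent probes. That is a smaller share than the 0.906% of all probes and the 3.16% of H3K4me3 probes that were enriched for H3K14ac. Probes with all 4 marks numbered 26 against 2.12 expected when each mark was called at its top 5%, again in 0 regions. At lower levels H2AFV followed H3K27me3: 34% of bivalent probes, 33.4% of all H3K27me3 probes and 4.85% of all H3K4me3 probes were among its top 5% of probes. Of the bivalent probes 71.6% were among the top 5% of H3K36me3 and 2.54% among those of H3K14ac. With 74 H2AFV probes enriched in all, in 2 runs of 3, a region was hardly possible at the threshold of 1. With the top 5% it was possible, but there H3K4me3 had to reach 2.08. Bivalent probes, whose median H3K4me3 was 1.56 at the threshold of 1, fell to 479. The top 5% therefore left out most bivalent chromatin, and its 0 regions say little about multivalent blocks.

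Across probes, H3K4me3 and H3K4me2 had the closest profiles of the histone tables, with a Pearson r of 0.92 and a Spearman rho of 0.91. H3K27me3 had an r of 0.61 with H2AFV and of 0.56 with H3K14ac, and H2AFV had 0.45 with H3K14ac. H3K36me3 had an r of 0.48 with H3K9me3. MeDIP in sperm had an r of -0.38 with H3K4me3 and -0.40 with H3K4me2. Shifted tables gave r between -0.03 and 0.04. The ChIP tables share a common input, and H3K14ac and H3K27me3 share arrays, so that part of these correlations may not come from the marks.

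**Figure D3:**
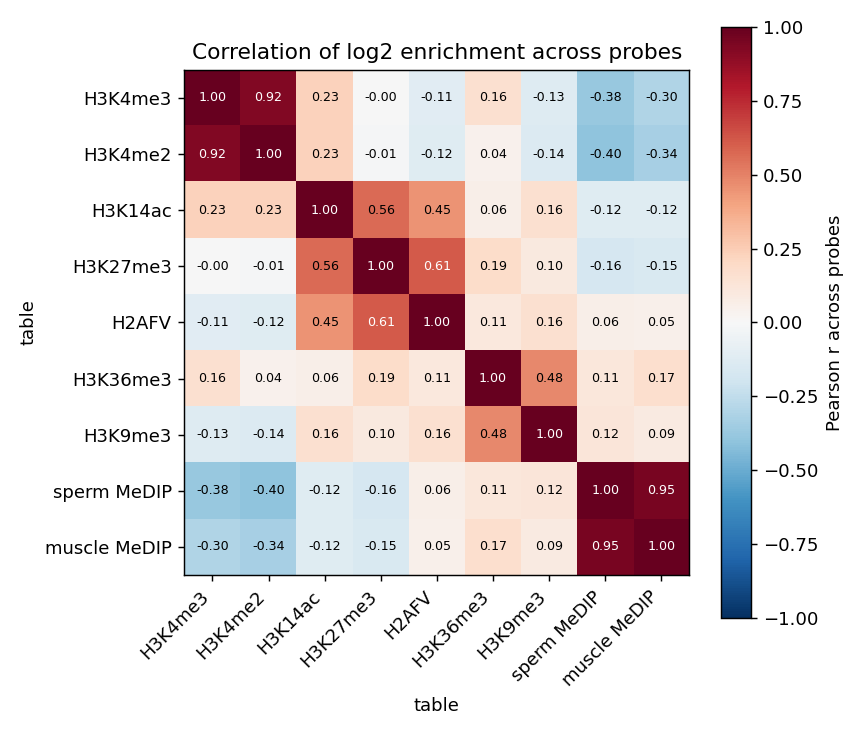
Pearson r across 339592 probes for each pair of the 9 tables (both axes), on a scale from -1 (blue) to 1 (red). H3K4me3 with H3K4me2 (0.92) and sperm with muscle MeDIP (0.95) are the closest pairs, and H3K4me2 with sperm MeDIP (-0.40) is the most opposed.

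MeDIP signal of sperm and muscle was close to alike over the array, and the probes that differed by at least 1 had mostly less signal in sperm. No correction for the sequence of the probes was made here, so that alike signal need not be alike methylation. The MeDIP tables had a Pearson r of 0.951 across probes, and 96.5% of probes differed by less than 0.5. Signal lower in sperm by at least 1 was found at 2295 probes (0.676%, 95% Wilson interval 0.649 to 0.704) in 287 regions, and higher signal at 353 probes (0.104%, 0.0937 to 0.115) in 12 regions. The probes lower in sperm had a median of -1.05 in sperm and 0.45 in muscle. Of these probes, 86.3% were enriched for H3K4me3, 33.3% for H3K27me3 and 36.9% for H3K36me3 in sperm chromatin. Among all probes the shares were 23.1%, 2.12% and 3.40%. Bivalent probes made up 31.2% of them, against 1.77% of all probes. Of the probes higher in sperm 13.0% were enriched for H3K4me3 and 0% for H3K27me3. Both sets were picked partly by their sperm signal, and low sperm signal itself went with H3K4me3 across all probes (r = -0.38). Shares set against all probes therefore cannot separate the difference from muscle from the level in sperm. No comparison with probes of like sperm signal was made. The 5 regions furthest below muscle had 3 to 5 probes and mean differences of -2.49 to -2.31, with H3K4me3 between 1.40 and 2.43. The 5 furthest above muscle had 3 to 5 probes and differences of up to 1.45. With a threshold of 0.5 the split was more even, at 6796 lower and 5194 higher. With quantile normalization the probes with MeDIP lower in sperm numbered 2106 and the probes with MeDIP higher in sperm 409; with 1 pooled value per tissue no difference has a replicate check.

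H3K4-methylated chromatin had low MeDIP signal, and bivalent chromatin had lower signal still in sperm. The median centred MeDIP value at H3K4me3 probes was -0.54 in sperm (-0.57 to -0.52 over 9 stretches of probes) and -0.39 in muscle (-0.42 to -0.37). At bivalent probes it was -0.84 in sperm (-0.98 to -0.78) and -0.44 in muscle (-0.57 to -0.30), and at H3K4me3 probes without H3K27me3 it was -0.52 and -0.39. Of bivalent probes 37.3% (95% Wilson interval 36.1 to 38.5) had a value of -1 or less in sperm and 13.9% (13.0 to 14.8) in muscle. Fewer than expected of the H3K27me3 probes were enriched in sperm MeDIP, 37 against 961.

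H3K36me3 marked chromatin of opposite MeDIP signal. Where it lay with H3K4me3, at 5305 probes, the median MeDIP value was -0.99 in sperm and -0.53 in muscle. Where it lay without H3K4me3, at 6239 probes, the median was 1.55 in sperm and 1.73 in muscle, and 69.6% of those probes were enriched in sperm MeDIP. Over all H3K36me3 probes the sperm median was 0.05, from -0.83 to 0.28 over 9 stretches of probes, and it was -0.02 and -0.17 with lower thresholds of enrichment (0.5, and the top 5% of probes). H3K14ac probes had medians of -0.40 in sperm and -0.29 in muscle, and H3K4me2 probes -0.45 and -0.33.

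**Figure D4:**
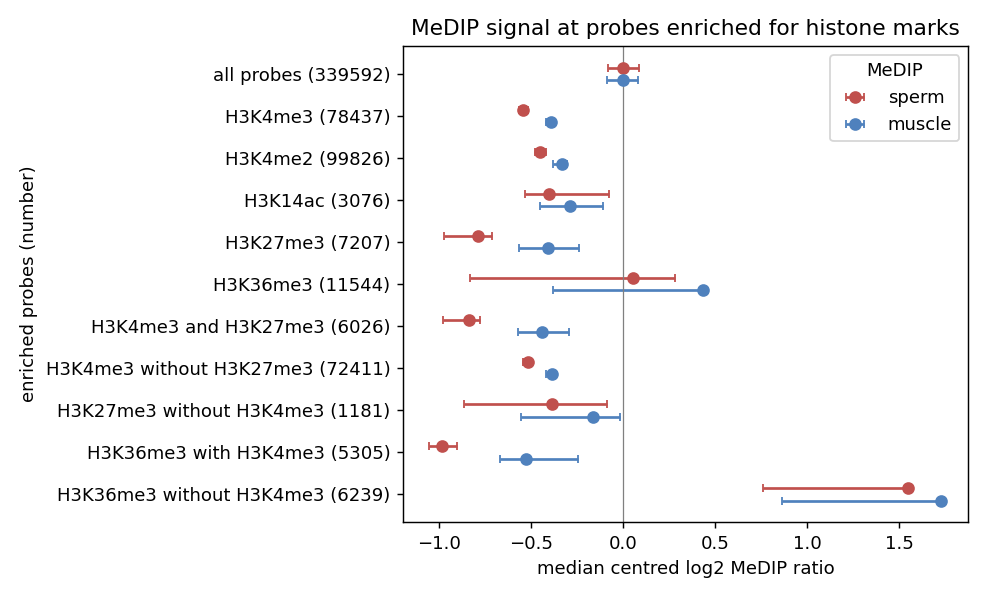
Points give the median centred log2 MeDIP ratio (horizontal axis) in sperm (red) and muscle (blue) at probes enriched for the histone marks named on the vertical axis with their number, and bars the range over 9 consecutive stretches of probes, extended to the median where it lies outside. Bivalent probes stand at -0.84 in sperm and -0.44 in muscle, and H3K36me3 probes without H3K4me3 at 1.55 and 1.73.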

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

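The spacing rules of neighbouring probes were tests chosen only after the data were seen; the other alternatives were planned. No paired analysis was possible because each RNA array sets sperm against the whole-fish reference directly and the chromatin tables hold pooled values with no replicate number. For RNA, low sperm signal over background limited what could be measured, and loess is what set the all-gene median near 0. With no background subtraction, no filter, outlier spots left out, the mean over probes, an added 2-fold minimum or an intensity trend the counts of genes stayed at 0, so that no call could turn. Uncalled values did change sign, with the mean over probes for gdf3 (-0.17) and calm1a (0.38), and with no background subtraction for genes near 0 such as gfap (-0.05). With Agilent's ratios 372 genes were higher and 2675 lower, and with median centring 77 and 5979, where the cause was not tested. With both channels above background 211 were higher and 7 lower. The named genes kept their ratios under that filter, and only their p-values changed. Lists higher numbered 2 at first and 4 with no background subtraction; lists lower numbered 1 with Agilent's ratios and 1 with median centring. With an estimated correlation 0 lists were higher and 0 lower, and with fry 0 and 0. With 2 arrays the estimated correlation could hardly have passed any list. With no test, genes at least 2-fold higher in sperm RNA on both arrays numbered 269 and genes at least 2-fold lower in sperm RNA 7. With an array left out, the counts on the remaining array alone ranged from 450 to 782 and from 7 to 156. Such counts on a single array do not compare with counts that require both arrays.

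Named genes with a ratio above 0 after loess that were called below 0 are given here; those already below 0 are left out. With Agilent's ratios they were cpe (-1.79), gdf3 (-2.05) and zp3a.1 (-1.59). With median centring they were vangl2 (-1.38), actb2 (-3.85), gfap (-0.68), cpe (-1.35), gdf3 (-6.76), her6 (-1.80), hmbsa (-1.87), gtsf1 (-3.59), piwil1 (-2.30), gapdhs (-2.55), pkma (-3.01), hoxb8a (-0.20), hoxc8a (-0.44), cd74a (-2.51), apoa1a (-6.05), hormad1 (-0.82), cox7c (-3.43), ndufa6 (-2.76), ybx1 (-5.29), zp3a.1 (-0.96), tlx2 (-2.21), klf2a (-2.09), rps27a (-4.78), rps14 (-4.27), krt5 (-5.06), krt4 (-4.02), star (-0.75), cyp17a1 (-2.31) and hsd3b2 (-0.56). The median of the ribosomal protein list was -4.80 there. These values lie on a scale whose all-gene median was -1.87; beyond that the cause was not tested.

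Counts of enriched probes moved with the threshold by construction, and the top 5% held 16980 probes of every table. H3K4me3 enriched probes numbered 48797 with values as deposited and 46816 at a threshold of 1.5, and H3K4me2 enriched probes 64323 with values as deposited. H3K14ac enriched probes numbered 144 at 1.5, 32092 at 0.5 and 1465 with smoothing, and H3K27me3 enriched probes 807 at 1.5 and 28808 at 0.5. H2AFV enriched probes numbered 2 at 1.5, 4925 at 0.5 and 10 with smoothing, and H3K36me3 enriched probes 3903 at 1.5 and 36857 at 0.5. H3K9me3 enriched probes numbered 128 with values as deposited, 23 at 1.5, 13601 at 0.5 and 77 with smoothing. For methylation, sperm MeDIP enriched probes numbered 13647 at 1.5 and 95959 at 0.5, and muscle MeDIP enriched probes 18666 and 91632.

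For H3K4me3 and H3K27me3 observed over expected was 4.49 at 1.5 and 1.69 at 0.5, and below 1 with the top 5% (0.564), where H3K27me3 is scarce among the highest H3K4me3 values. For H3K4me3 and H3K14ac observed over expected was 5.04 with values as deposited, 5.94 at 1.5, 1.85 at 0.5, 6.91 in the top 5% and 4.07 with smoothing. For H3K14ac and H3K27me3 observed over expected turned above 1 at 0.5 (1.48) and in the top 5% (1.26) and was 0.154 with smoothing; the cause was not tested. For H3K27me3 and H3K36me3 observed over expected was 21.1 at 1.5, 3.93 at 0.5, 7.73 in the top 5% and 17.8 with smoothing. H2AFV with H3K27me3 at 1.5 and with smoothing, and H3K14ac with H3K27me3 at 1.5, were left without a value because fewer than 1 probe was expected. The bivalent regions numbered 494 with values as deposited, 25 at 1.5, 1534 at 0.5, 41 in the top 5%, 351 with at least 5 probes and 1159 with at least 2. Multivalent regions were 0 under each of these, with 1 missed probe, and with numbers differing by 1 or by up to 5. With so few H2AFV enriched probes, only the setting of 0.5 could well have given any. The top 5% left few bivalent probes in which a multivalent region could lie.

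With smoothing, probes with MeDIP higher in sperm numbered 112; they numbered 5194 at 0.5 and 18 at 1.5, and regions with MeDIP higher in sperm 389 and 0. At the same thresholds, probes with MeDIP lower in sperm numbered 6796 and 832, and regions with MeDIP lower in sperm 761 and 71. The MeDIP median at H3K4me3 probes in sperm was -0.74 with values as deposited, -0.65 at 1.5, -0.41 at 0.5 and -0.75 in the top 5%, and in muscle -0.55, -0.49, -0.29 and -0.60. At H3K27me3 probes it was -0.89 in sperm at 1.5, -0.33 at 0.5 and -0.56 in the top 5%, and in muscle -0.16 at 0.5 and -0.27 in the top 5%. The median sperm MeDIP at H3K36me3 probes turned below 0 at 0.5 (-0.0175) and in the top 5% (-0.17); the cause was not tested. A wider gap in base pairs, the promoter windows at gene lists, their summary, and chromatin by sperm RNA were not run, since probe positions were not used here.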

Other observations

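The comparison of leukocyte with erythrocyte genes and both tests along the probe order were tests chosen only after the result was seen; the macrophage and neutrophil lists were written after the leukocyte genes had been seen and before the values of their own members were.

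Genes of the added macrophage list, but not of the added neutrophil list, were bright in sperm RNA after loess. The added lists were not run with median centring. Of 20 measured members of the added macrophage list, 14 were above background in sperm on both arrays. The lysosomal saposin precursor psap had a log2 ratio of 3.86 ± 1.31 (SD, n = 2), the progranulin gene grna 2.88 ± 1.85, the actin-capping gene capgb 2.93 ± 1.53 and the complement gene c1qb 2.64 ± 2.47. Array 1 was higher for 16 of the 20 genes, with a median of 2.95 against 0.89 on array 2, whereas for ribosomal proteins array 1 was higher for 7 of 62 genes, with medians of 1.11 and 2.19. The 5 measured members of the added neutrophil list had a median of -0.04, with 0 above background in sperm on both arrays. No tested macrophage gene is in another list (0 of 20). By limma 0 genes of either added list passed an adjusted p of 0.05.

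A candidate explanation for the bright leukocyte genes is RNA of macrophages or related cells in the sperm preparation, which per the labels was screened under a microscope. The median of the macrophage list, without the members of the leukocyte list, was 2.03 and lay at percentile 100 of 10000 random lists matched on intensity, whose 95th percentile was 0.25, but the measure was extreme for other lists too: the ribosomal protein, sperm and flagellum and leukocyte lists also lay at percentile 100, skeletal muscle at 0 and liver and plasma at 0.12. Whole blood as the source stays open: the median of the erythrocyte list lay 1.40 below that of the leukocyte list, less than the spread of 1.73 between members (both lists), and the globin genes went opposite ways, with hbba1 at least 3.58-fold dimmer and hbbe2 at least 3.42-fold brighter in sperm. Lysosomal genes are also used by other cell types, so transcripts of the sperm themselves or of testis cells that take up debris stay open. These sources were not tested, and the design holds no group of macrophages or testis cells that could tell the sources apart.

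H3K14ac and H3K27me3 rose and fell together across probes (r = 0.56), although probes enriched for both were not in excess, at 54 against 65.3 expected. The correlation may come from noise shared through common arrays and a common input. True marks extend over neighbouring probes, and between neighbours the correlation, corrected for how far each mark extends, was 0.146, which is 0.417 below that at the same probe. Such a drop is what shared noise predicts, although H3K14ac and H2AFV, which by the labels share no arrays, also went from 0.449 to 0.137, so that common arrays are not singled out from the common input. The corrected value was 0.0139 at a distance of 2 probes, -0.0788 at 3 and -0.163 at 5, so that little was left beyond neighbours. No biological explanation was tested.

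H2AFV and H3K27me3 also rose and fell together across probes (r = 0.61), and here the relation held over a distance. The corrected correlation was 0.496 between neighbours and 0.440 at a distance of 3 probes, and the uncorrected values were 0.219 and 0.132. Noise confined to single probes is argued against as the only source. The test takes noise from the common input as local, so that it cannot decide on input signal that itself extends along the probes. A shared distribution of this variant and H3K27me3 is consistent with these values, as is a property of the DNA or of the nucleosomes that shifts both tables along the genome, which was not tested.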
